A study of Caenorhabditis elegans with 4 samples.

How the data were processed

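RNA polymerase II was immunoprecipitated with the 8WG16 antibody from formaldehyde-crosslinked L3 hermaphrodites of strain OP54, and input DNA was kept from the same kind of lysate, per the labels. The series held 2 ChIP samples and 2 input samples. Per the deposited sample table, 8 sequencing runs of 36 bp reads were made, 3 of ChIP DNA and 5 of input DNA, and the deposited description of the series names ELAND for alignment. The versions of the aligner and the peak caller are not given in the sources used here.

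Per the deposited sample table, the authors gave each run its total read count and its uniquely mapped read count, and the count of reads mapped to more than one place was 0 in every run. Such reads may have been discarded or not counted, so the reads that did not map uniquely cannot be called unmapped. Each run is listed in the deposited sample table once per peak calling step and was counted once here. Peaks were called with PeakSeq, per the source column of the deposited lists. Per the deposited sample table, this was done on the reads of each ChIP replicate and on the merged reads of both, each time against the merged input of both input samples. PeakSeq finds regions with more ChIP reads than a background model allows and scores each against the control. The authors' value for each peak is a q-value, as the attribute column of the deposited lists names it, and the deposited lists hold q-values up to 0.00999. No list holds a q-value of 0. These q-values were used to rank, filter and describe peaks within a list and, for overlapping pairs, to compare their order between the replicates. Coordinates are in WormBase WS220, per the file headers; comment lines in the files record that features were carried over from an earlier build, and mark 4 features in the combined list, 4 in replicate 1 and 2 in replicate 2 as changed in doing so.

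The pooled list has no replicate error of its own, so the spread was taken from the replicate lists, as mean ± SD (n = 2). Shares were given exact (Clopper-Pearson) 95% intervals. Chromosome lengths of WS220 were not used here; each chromosome's span was taken from its first base to the last base of any peak in the 3 lists, between 13.8 Mb for III and 20.8 Mb for V and 100.0 Mb in all. Overlap was counted from 1 bp. Chance overlap was estimated from 10000 random circular shifts of one list along each chromosome, with a one-sided permutation p, and from 1000 shifts for each alternative. Rank and linear correlations of −log10 q were computed over pairs of each replicate 1 peak with the replicate 2 peak of largest overlap, with 100000 resamples. Peak counts per chromosome were set against the chromosome's share of the span by a two-sided exact binomial test, with Benjamini-Hochberg adjustment over the 6 chromosomes, and, chosen after the data were seen, against the span without chromosome I, adjusted over the other 5. Peaks with q under 1e-50 were compared with peaks with q between 1e-50 and 1e-10 by Fisher's exact test, a split chosen after the data were seen.

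The comparisons between replicates, lists and chromosomes and their tests were chosen before the data were examined, and so was the rule for the peaks named by position: the 10 combined-list peaks with the smallest q that overlap both replicates, and the 5 widest. Other peaks named in the text were chosen after their values were seen. The alternatives set beforehand were overlap of 50% of the replicate 1 or combined-list peak or of both peaks, the peaks with the smaller q values of each list (up to its median), local shifts of 20 to 200 kb, pairs matched one to one, clusters of peaks within 10 kb, base pairs in place of counts, and each replicate list in place of the combined one. The share of peaks at gene starts, lists of bound genes and density per gene of WS220 were also planned, and were not run because no annotation of that build was used here. A gene table of assembly WBcel235 served only to count protein-coding genes per chromosome; none of its coordinates was used.

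The overlap test was tested on simulated data. In 100 pairs of randomly placed lists with the real numbers of peaks (1065 and 1220) and widths, 7 reached a permutation p under 0.05 and the median ratio of observed to shifted overlap was 1.01. The binomial test of the X count passed 0.05 in 7 of the 100. Peaks were placed there independently and in proportion to the span, so the rate for X was fixed by the simulation. The clustering and uneven spread of the real peaks were not simulated, so neither rate need hold for the real lists. With 50.1% of replicate 1 peaks planted in replicate 2, the overlap came out at 51.7%. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.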

Results

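Binding of RNA polymerase II was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in Caenorhabditis elegans hermaphrodites at the L3 larval stage, grown at 20 °C. The worms were of strain OP54, an unc-119 mutant rescued by a transgene that carries unc-119 and a tagged copy of egl-5, a Hox gene that patterns the posterior body. The antibody, 8WG16, recognises the heptapeptide repeat at the C terminus of AMA-1, the largest subunit of the polymerase. The 4 samples fell into 2 groups of 2, polymerase ChIP and input DNA, and the design holds no contrast between conditions. The comparisons it implies are between the ChIP replicates, between each of them and the peak list called on their merged reads, and between chromosomes.

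Replicate 1 of the ChIP had 4922526 reads, of which 1959480 mapped uniquely (39.8%, exact 95% interval 39.76 to 39.85). Replicate 2 had 4144392 reads and 2364309 unique ones (57.0%, interval 57.0 to 57.1). The input samples were sequenced more heavily, with 9237603 and 10363085 reads, but 11.7% (interval 11.7 to 11.8) and 7.50% (interval 7.48 to 7.51) of them mapped uniquely. The merged input that served as the control for every list therefore held 1861526 unique reads, and the merged ChIP reads were 2.32 times as many. These intervals cover counting error only.

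Polymerase peaks covered a few percent of the genome in every list. The combined list, called on the merged ChIP reads, held 1758 peaks that covered 3.49 Mb, or 3.49% of the span between the chromosome starts and the last peaks. The replicate 1 list held 1065 peaks (2.27% of the span) and the replicate 2 list 1220 (2.65%). Median widths were 1215 bp in the combined list (quartiles 464 and 2921), 1468 bp in replicate 1 and 1570 bp in replicate 2. The combined list also held 47 peaks narrower than a 36 bp read, against 10 and 19 in the replicate lists.

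The first question was how far the replicates located the polymerase at the same places. Of the 1065 replicate 1 peaks, 727 overlapped a replicate 2 peak by at least 1 bp (68.3%, exact 95% interval 65.4 to 71.1), which was 11.8 times the 5.81% that random shifts of the replicate 2 peaks gave. In the other direction 718 of 1220 replicate 2 peaks overlapped replicate 1 (58.9%, interval 56.0 to 61.6), or 11.3 times the shifted value. The overlap of replicate 1 peaks was lowest on X (59.8%, interval 49.6 to 69.4) and highest on III (73.9%, interval 64.7 to 81.8), and these intervals overlap. In both directions the one-sided permutation p was 0.0001, the smallest that 10000 shifts can give. Both lists were called against the same merged input, so part of the overlap may come from that control, and the labels do not say whether the replicates came from separate cultures.

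Whether a replicate 1 peak was found again depended on its strength, and not in one direction. The share overlapped by replicate 2 was 55.7% of 512 peaks with −log10 q between 2 and 5, 86.6% of peaks between 20 and 50, and 86.9% of 61 peaks between 50 and 100. Above that it fell, to 60.0% of 35 peaks between 100 and 200 and to 2 of the 8 peaks at 200 or more. The peak with the smallest q of replicate 1, at V 6220722 to 6231140 (q 1.55e-283), had no partner in replicate 2 or in the combined list. Whether a strong peak without a partner was not bound in replicate 2 or was left out of the replicate 2 list cannot be read from these files, so the fall is not a measure of failed replication. Replicate 2 showed no such fall, since all 75 of its peaks with −log10 q of 100 or more overlapped replicate 1.

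Across the 727 overlapping pairs, the replicates ordered the peaks alike to a moderate degree. Spearman's rho of −log10 q was 0.586 and Pearson's r 0.600 (two-sided permutation p of 1e-05 for each, the smallest that 100000 resamples can give). The q was the smaller in replicate 2 in 525 pairs (72.2%), and the median −log10 q of the pairs was 14.7 there against 7.13 in replicate 1. A replicate 2 peak paired with several replicate 1 peaks was counted once for each, which widened this gap. In the 613 pairs matched one to one the medians were 11.7 in replicate 2 and 6.76 in replicate 1. Replicate 2 also had 1.21 times the unique reads of replicate 1, and q values fall with depth at a fixed enrichment. How much of the difference in q came from depth was not tested. The correlation is across peaks, which are not independent replicates.

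**Figure D1:**
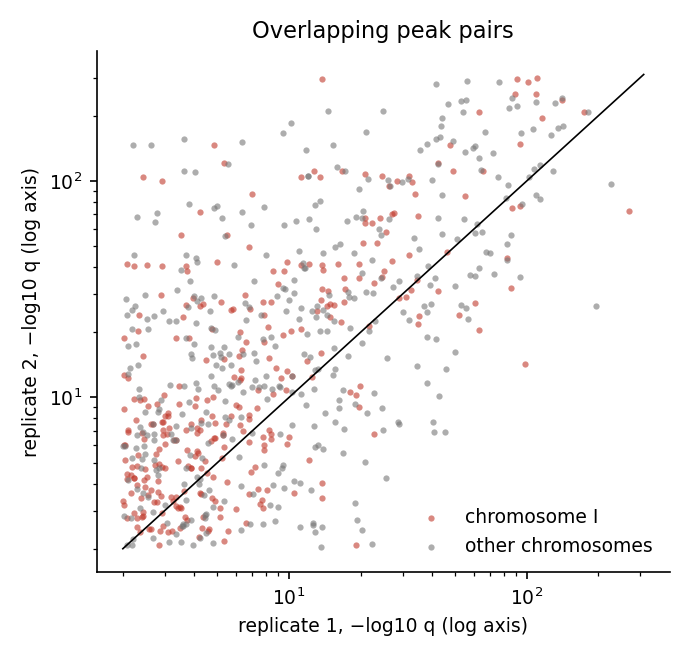
Each point is one of the 727 overlapping pairs of peaks, with −log10 q in replicate 1 on the horizontal axis and in replicate 2 on the vertical axis, both logarithmic, red for chromosome I and grey for the rest. Of the pairs, 525 lie above the line of equal values, and rho was 0.586.

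The combined list was strongest where both replicates had a peak. Of its 1758 peaks, 642 overlapped a peak of both replicates (36.5%, exact 95% interval 34.3 to 38.8), 225 overlapped replicate 1 alone, 434 replicate 2 alone and 457 (26.0%) neither. Peaks found in both had a median width of 2705 bp and a median −log10 q of 29.2, while those found in neither had medians of 387 bp and 2.74. In the 879 peaks with the smaller q values of the list, 70.0% were found in both and 8 in neither. The combined list rests on the same reads as the replicate lists and is not independent of them.

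Conversely, the strongest replicate peaks were often missing from the combined list. Weak peaks were missing too, 14.1% of replicate 1 and 10.6% of replicate 2 peaks with −log10 q between 2 and 5, but fewer were missing between those and the strongest. Of the replicate 1 peaks with q under 1e-50, 44 (42.3%) had no combined-list peak, against 3 of 259 with q between 1e-50 and 1e-10 (1.16%; Fisher's exact test across peaks, p = 3.81e-24). In replicate 2 these numbers were 21 of 144 (14.6%) and 2 of 339 (0.590%; Fisher's exact test, p = 4.33e-10). Among the 10 peaks with the smallest q, 9 were missing in each replicate. The missing peaks formed 45 regions that together spanned 274 kb, 13 of them on I, 4 on II, 4 on III, 2 on IV, 13 on V and 9 on X. Any ranking by the combined list therefore leaves out regions that were among the strongest in a replicate.

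**Figure D2:**
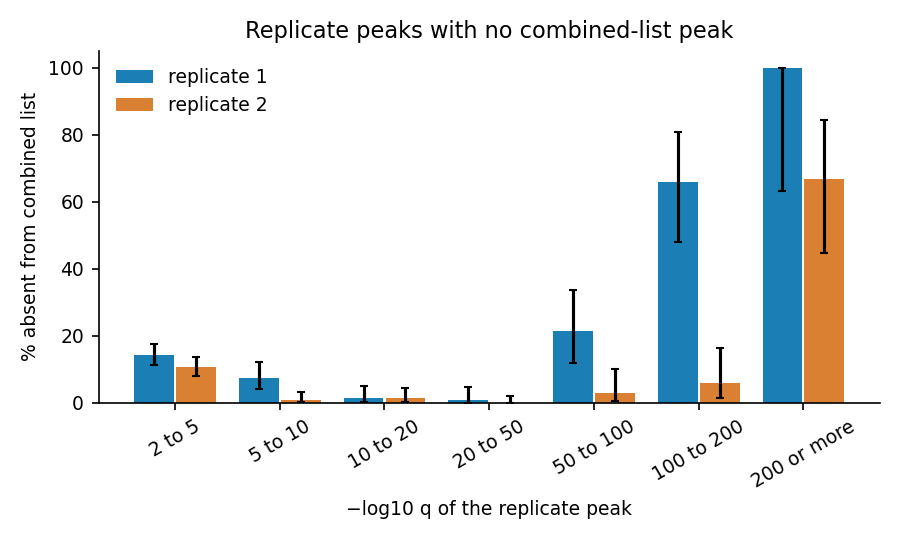
Bars show the percentage of replicate peaks with no overlapping combined-list peak, by the −log10 q of the replicate peak, and error bars are exact 95% binomial intervals. The share is 0.840% for replicate 1 peaks between 20 and 50 and reaches 100% for the 8 peaks at 200 or more, and in replicate 2 it reaches 66.7% of 24 peaks.

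**Figure D3:**
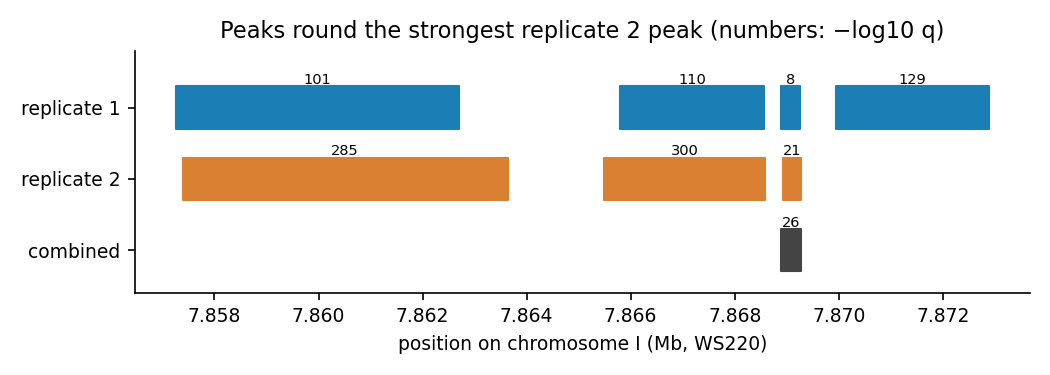
Boxes are peaks of the 3 lists on chromosome I around the strongest replicate 2 peak (7865485 to 7868574, q 1.75e-300), with −log10 q above each box and position in Mb on the horizontal axis. That peak and the one at 7857393 to 7863633 (q 8.4e-286) are in both replicate lists and not in the combined list, which keeps the weaker peak between 7868881 and 7869272 (q 7.26e-27).

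Of the combined-list peaks shared by both replicates, the 10 with the smallest q lay on 5 chromosomes, 3 each on I and IV. The first was at III 5501171 to 5506863, 5.69 kb wide, with a q of 1.81e-304, and its replicate q values were 4.52e-56 and 1.12e-237. It was followed by I 6835298 to 6838738 (q 2.95e-296), IV 3644678 to 3649323 (q 1.45e-294), I 2583806 to 2589993 (q 2.84e-293) and II 6888032 to 6892995 (q 7.9e-285). The others were at II 5659477 to 5664093, X 13143048 to 13146421, IV 16167101 to 16171662, IV 9438574 to 9445686 and I 526934 to 533968, with q values between 2.75e-274 and 8.84e-248. In all 10 the q was smaller in replicate 2 than in replicate 1. The smallest replicate 1 q at each of the 10 ranged from 1.92e-14 to 3.16e-182, and that of replicate 2 from 2.14e-149 to 2.55e-295. The gap was large at I 6835298 to 6838738, with a q of 1.92e-14 in replicate 1, whose peak ended at 6836438, and 2.55e-295 in replicate 2.

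The 5 widest peaks of the combined list were domains of 13.9 to 20.4 kb, each overlapped by both replicates. Replicate 1 alone held a peak of 18655 bp, at II 10541830 to 10560484 (q 1.11e-244), with no partner in the other lists. The widest, at III 7718327 to 7738738, measured 20412 bp in the combined list (q 1.5e-93) and was 1 peak in replicate 1 and 3 separate peaks in replicate 2. The next were IV 14609525 to 14624450 (14.9 kb, q 4.14e-114), II 1232967 to 1247688 (14.7 kb, q 2.38e-10), V 10711692 to 10725822 (14.1 kb, q 7.38e-94) and V 10463846 to 10477727 (13.9 kb, q 6.91e-69). The domain on II was weaker in the combined list than in replicate 1 alone, where its q was 1.32e-19, and its replicate 2 q was 0.000549. All positions are in WormBase WS220. Peaks were not assigned to genes, since the gene table used here is of another assembly (WBcel235), so egl-5, unc-119 and ama-1 were not placed either.

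Polymerase peaks were spread unevenly over the chromosomes, with a large excess on I. Chromosome I carried 806 of the 1758 combined-list peaks (45.8%, exact 95% interval 43.5 to 48.2), though it makes up 15.04% of the span (exact binomial test, Benjamini-Hochberg adjusted over 6 chromosomes, p = 1.44e-205). That is 53.6 peaks per Mb, against 15.5 on III, 12.6 on II, 12.6 on IV, 8.54 on V and 8.43 on X. The replicate lists gave a share of 41.6% ± 0.774 (SD, n = 2) and a density of 31.6 ± 2.44 peaks per Mb on I, and the next highest mean was 9.88 ± 2.57 on III (SD, n = 2). Since the shares sum to 100%, the shortfalls of the other chromosomes against the whole span partly restate this excess, so they were also set against the span without I, a test chosen after the data were seen. Among the 952 combined-list peaks off I, III lay above its share (22.4% of peaks against 16.2% of the span, exact binomial p adjusted over 5 chromosomes = 3.84e-06), though in replicate 1 its 18.02% did not pass (adjusted exact binomial p = 0.229). V (18.7% against 24.5%, adjusted exact binomial p = 5.02e-05) and X (15.7% against 20.8%, adjusted exact binomial p = 0.000106) lay below their shares, V with an adjusted exact binomial p of 0.0519 in replicate 1. II and IV did not pass in the combined list (adjusted exact binomial p = 0.0758 and 0.0677), while IV lay above its share in both replicate lists (adjusted exact binomial p = 0.0317 and 0.0231). Neighbouring peaks are not independent, so all these binomial p-values are too small to an unknown degree. The replicate lists also share the merged input as control.

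By their medians, peaks on chromosome I were narrower and weaker than those elsewhere, except that its few peaks with −log10 q of 100 or more were not narrower. The median width on I was 621.5 bp, against 2132.5 bp on the other chromosomes, and the median −log10 q was 5.28 against 8.33. Among peaks with −log10 q between 50 and 100 the median width was 3000 bp on I (40 peaks) and 4788 bp elsewhere. Between 100 and 200 it was 4600 bp on I (27 peaks) and 4183 bp elsewhere, and at 200 or more 5313.5 bp on I (4 peaks) and 4631.5 bp elsewhere. The chromosome I share was 52.9% of the 729 combined-list peaks with −log10 q between 2 and 5 and 32.1% of the 221 peaks with q under 1e-50 (exact 95% interval 26.0 to 38.7). Of the 22 peaks with −log10 q of 200 or more, 4 lay on I (18.2%), near its 15.04% of the span. These 22 are a remainder, since 9 of the 10 peaks with the smallest q in each replicate are missing from the combined list. Of the 45 missing strong regions, 13 lay on I, so the share on I among all the strongest peaks is not known. Counted by base pairs, chromosome I held 26.8% of the covered length. Replicate 1 peaks on I overlapped replicate 2 in 71.0% of cases (interval 66.6 to 75.2), against 66.2% on the other chromosomes. Shifted peaks overlapped more often on the denser chromosome I (7.79%, against 4.36% elsewhere), so its ratio of observed to shifted overlap, 9.12, was the lowest of the 6 chromosomes, the others lying between 13.3 and 18.5.

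**Figure D4:**
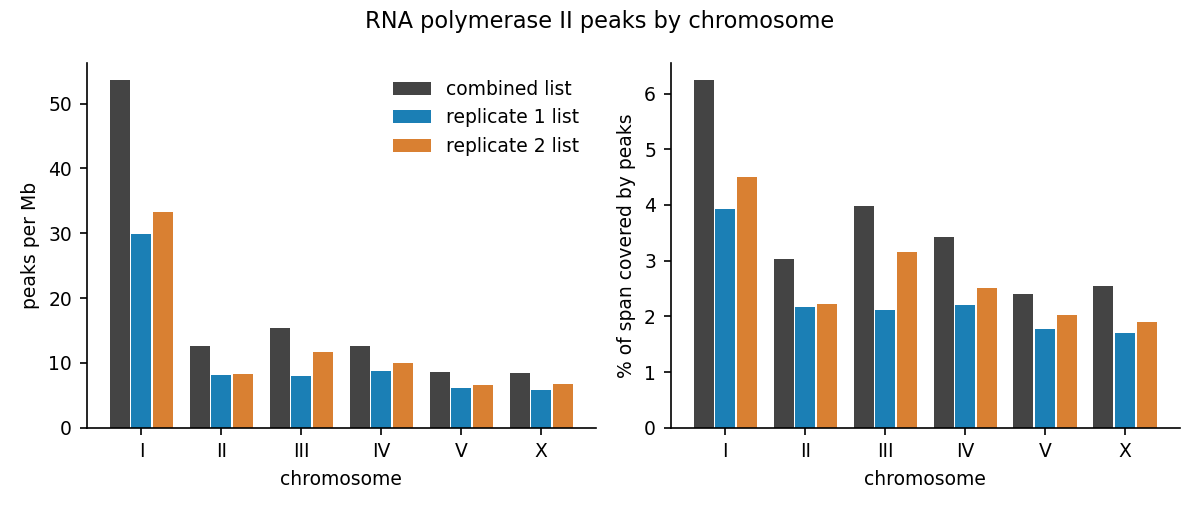
Bars show, for each chromosome and list, peaks per Mb of span (left) and the percentage of the span covered by peaks (right). Chromosome I stands at 53.6 peaks per Mb in the combined list and 6.24% covered, and the other chromosomes lie between 8.43 and 15.5 peaks per Mb and between 2.40% and 3.98% covered.

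Per Mb, the X chromosome carried fewer peaks than the autosomes, and per gene it carried about as many as II to V. In hermaphrodites, which have a pair of X chromosomes, the dosage compensation complex lowers transcription of X, so the density of polymerase peaks on X is a comparison of interest in its own right. A count of peaks does not measure how much polymerase lies at each of them. The combined list held 149 peaks on X, or 8.43 per Mb, against 19.5 per Mb on the 5 autosomes, a ratio of 0.432 (exact 95% interval 0.362 to 0.511, two-sided exact binomial p = 4.91e-28). The replicate lists gave 0.501 ± 0.0105 (SD, n = 2). Much of this difference came from chromosome I: against II to V alone, a comparison chosen after the data were seen, the ratio was 0.707 (interval 0.589 to 0.843, exact binomial p = 6.33e-05) and 0.760 ± 0.00509 in the replicates (SD, n = 2). Counted per protein-coding gene named in the WBcel235 table, also chosen after the data were seen, the ratio was 0.585 to all autosomes (interval 0.491 to 0.692, exact binomial p = 2.22e-11) and 0.976 to II to V (interval 0.814 to 1.16, exact binomial p = 0.825) and 1.05 ± 0.00703 in the replicates (SD, n = 2), so a deficit per gene was detected only with chromosome I included. The SDs of these ratios understate their error, since the counting error of each replicate list was much larger. Against II to V, the interval per gene was 0.836 to 1.29 in replicate 1 and 0.859 to 1.28 in replicate 2. Per Mb it was 0.605 to 0.937 and 0.622 to 0.930. The pooled value per gene covers unlike chromosomes. Per 100 protein-coding genes the combined list held 5.46 peaks on X, against 5.57 on II, 8.06 on III, 6.71 on IV and 3.56 on V. In both replicate lists too, X lay below III and IV and above V per gene. These differences between single chromosomes were not tested. Per Mb, X was close to V, which had 8.54 peaks per Mb in the combined list and 6.36 ± 0.305 in the replicates (SD, n = 2), against 6.28 ± 0.720 on X. Peaks are not independent along a chromosome, so the binomial p-values are too small to an unknown degree.

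**Figure D5:**
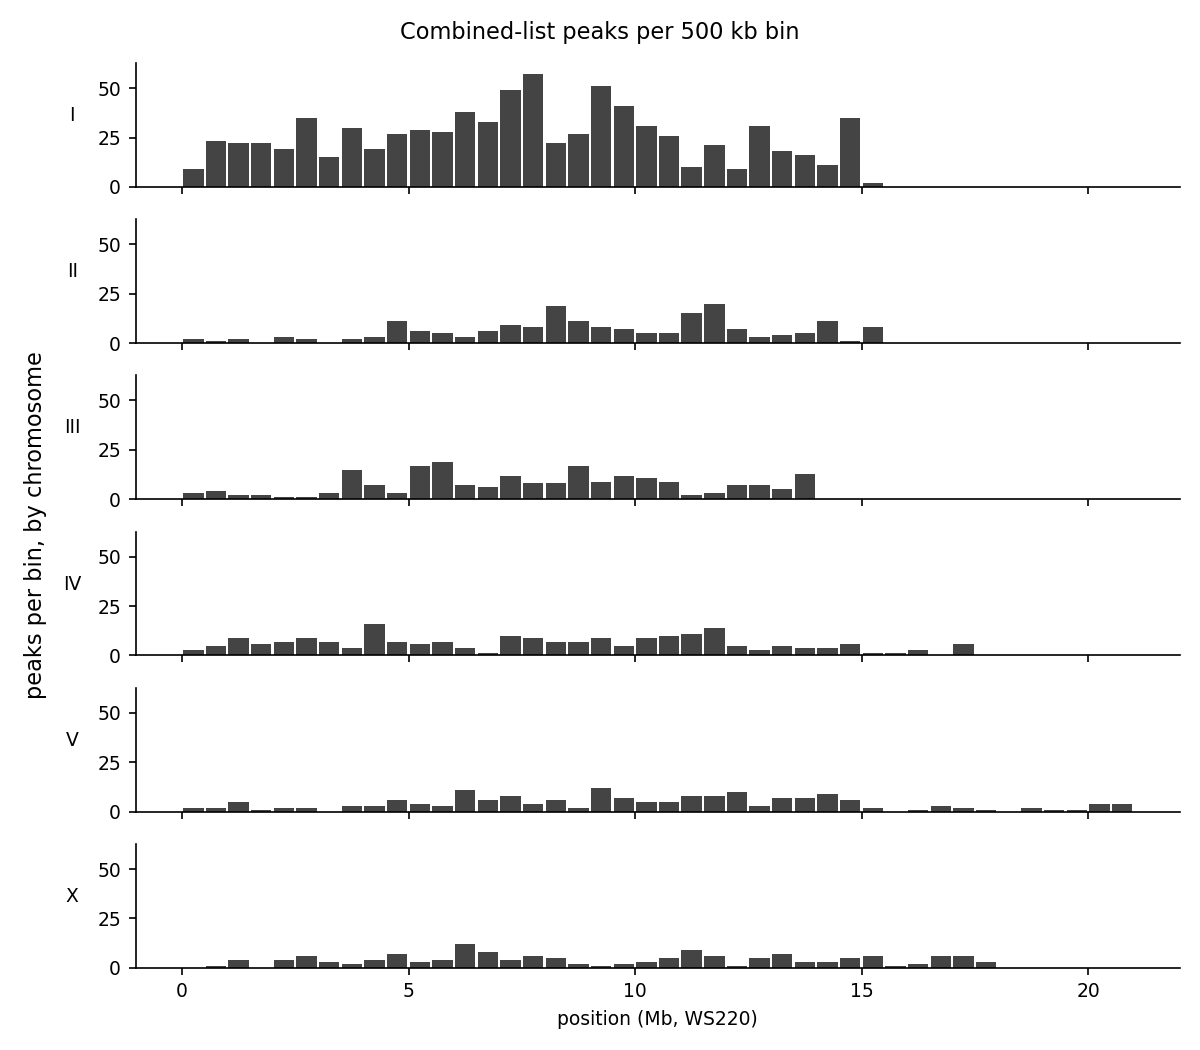
Bars count combined-list peaks in 500 kb bins along each chromosome, with position in Mb on the horizontal axis and the same vertical scale in every panel. Peaks on I lie along the whole chromosome, and 62.7% of them fall in its central 50%.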

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

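Settings without chromosome I, those for the share on chromosome I, those restricted by a q of 1e-50, the counts per gene and the demand that 50% of the replicate 2 peak be covered were chosen after the data were seen. The overlap between replicates stayed above the shifted value in all 12 alternatives, from 46.6% (50% of both peaks covered, replicate 2 peaks asked about) to 68.5%, and rho stayed positive in all 4, from 0.340 in the pairs of higher rank to 0.695. The pairs of higher rank were selected on the summed ranks of both replicates, which by itself lowers rho. The value of 0.340 therefore does not show poorer agreement among strong peaks. The share of combined-list peaks found in both replicates moved from 36.5% to 29.3% when 50% of the peak had to be covered in each, to 70.0% among the peaks with the smaller q values and to 39.5% without chromosome I; the first follows from the stricter demand and the next from the removal of weak peaks, and the cause of the last was not tested. The ratio of X to autosomes stayed below 1 in all 10 alternatives. Of these, the 2 by base pairs have no test, and of the 8 with a test 1 no longer passed, per gene and without chromosome I (0.976, exact binomial p = 0.825), where genes are fewer per Mb on X than on II to V; the single replicate lists then gave 1.04 and 1.05. It was 0.611 with peaks within 10 kb merged, 0.689 by base pairs covered, 0.585 per protein-coding gene named in WBcel235, and without chromosome I 0.707 by peaks, 0.767 by merged peaks and 0.814 by base pairs. With a single replicate list it was 0.494 to 0.508. Chromosome I kept more than its 15.04% of the span in all 8 alternatives, with 41.1% to 42.2% in the single replicate lists and 26.8% of base pairs covered, where narrow peaks count for less. No paired analysis was possible because the input samples have no peak list of their own. Windows at gene starts and lists of bound genes were not run, for want of an annotation of the build used. Leaving out a replicate gives no overlap or correlation. The effect of read depth or control depth on the calls was not tested.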

Other observations

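The tests of explanations in this part were all chosen after the results were seen. Over autosomes II to V, polymerase peaks lay mostly in the chromosome centres. On II to V, 528 of 803 combined-list peaks had their midpoint in the central 50% of the span (65.8%, exact 95% interval 62.4 to 69.0), more than under random rotation of each chromosome (one-sided permutation p = 0.0034), and the replicate lists gave 66.2% ± 3.21 (SD, n = 2). The share was highest on V (74.2%) and lowest on IV (59.1%), and merging peaks within 10 kb left 65.5% on II to V. On IV the central share in replicate 2 did not pass the threshold (54.6%, interval 46.9 to 62.1, exact binomial p = 0.255), and on I it was 62.7%, or 56.5% after merging. Autosome centres of this worm are known to be rich in widely expressed genes and the arms in repeats, so more polymerase in centres is one hypothesis, while poorer unique mapping in the arms could give the same picture and was not tested. On X, 58.4% of 149 peaks were central (interval 50.0 to 66.4), with 51.96% in replicate 1, 58.3% in replicate 2 and 54.6% after merging, and the difference from II to V did not pass the threshold (Fisher's exact test across peaks, p = 0.0932). Rotated in the same way, the combined list gave a one-sided permutation p of 0.0424 on X and 0.038 on I. Both lay just under the threshold of 0.05, so a central concentration was not confined to II to V in that list.

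For the strong replicate peaks missing from the combined list, loss of peaks carried by a single replicate is argued against for replicate 2, where 100% of the 21 missing strong peaks overlapped a replicate 1 peak. In replicate 1 strong peaks without a partner were missing more often (24 of 28) than those with one (20 of 76), but of its peaks without a partner and with q between 1e-50 and 1e-10, which merging should dilute more, 5.26% were missing (2 of 38). Loss on moving features between builds is argued against as well, because 0.590% of replicate 2 peaks with q between 1e-50 and 1e-10 were missing against 14.6% with q under 1e-50. A candidate explanation is that peaks whose q was too small to be written as a number were left out: no list holds a q of 0, the smallest is 1.81e-304, and from a −log10 q of 50 upwards the missing share rose with strength, although 8 of the 24 replicate 2 peaks with −log10 q of 200 or more are in the combined list. The same omission may apply to the replicate 2 list, where strong replicate 1 peaks were missing too, and no biological explanation was tested.

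The excess on chromosome I was present in both replicates. Broken-up regions do not account for it alone, since chromosome I kept 30.9% of the clusters made by merging peaks within 10 kb (exact 95% interval 28.1 to 33.8), although it had 2.54 peaks per cluster against 1.25 to 1.49 elsewhere. Scattered false calls are argued against as the whole cause by the replicates, which overlapped on I 8.75 times as often as after local shifts, although this ratio was the lowest of the 6 chromosomes (11.5 to 16.8 on the others) and part of the weak calls stays open. That test used replicate 1 peaks. In the combined list 26.0% of all peaks were found in neither replicate, and 20.9% of those off I, so such peaks were more frequent on I. Of its 642 peaks found in both replicates, 41.4% lay on I. Gene number is argued against too: I had 28.0 peaks per 100 protein-coding genes named in WBcel235 and II to V 5.59, a ratio of 5.01. A low control level on I, which every list shares through the merged input, cannot be told apart from more polymerase on I, since both would raise strong peaks too (32.1% of peaks with q under 1e-50 lay on I) and control reads per chromosome were not analysed here. At −log10 q of 200 or more the share on I was 18.2% (4 of 22 peaks), too few to show an excess among the strongest peaks. It also does not show that the excess ends there, because the combined list lacks most of the strongest replicate peaks. Of the 45 missing strong regions, 13 lay on I.

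The input runs differed from the ChIP runs in how many reads mapped uniquely. The 5 input runs lay between 6.30% and 13.4%, and the 3 ChIP runs between 35.1% and 57.0%. In input replicate 2, 1 of the 3 runs carried the index sequence of the input replicate 1 runs in its name, and its uniquely mapped share was 9.25%, against 7.51% and 6.30% in the other runs of that sample and 10.4% and 13.4% in the runs of input replicate 1.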
